A study of Homo sapiens with 6 samples.

How the data were processed

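RNA was measured by sequencing of ribosomal RNA-depleted libraries from xenografts of HCT116, an established human colorectal carcinoma line that carried luciferase here. The cells were injected into the liver of mice, so that the tumours model colorectal liver metastases. The labels name 3 libraries as bevacizumab-sensitive (treatment label Day 0) and 3 as bevacizumab-resistant (treatment label Day 42). Bevacizumab is an antibody against the growth factor VEGF-A. Per the labels' protocols, animals were randomised on day 7, the treated arm received 10 mg/kg by intraperitoneal injection for 7 weeks, and the vehicle arm received IgG. The label of Day 42 and the protocol's 7 weeks stand side by side as given. The labels do not say that each library came from a separate animal, so p-values measure the spread between these samples, which may be technical.

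The authors deposited FPKM values (fragments per kilobase of transcript, scaled to each library's fragments) of long non-coding transcripts for each library, per the file headers. These came in 3 tables, each holding the resistant and the sensitive library of the same number, and a pooled table that held the mean of each group. The authors' log2 fold changes and p-values, raw and adjusted, stood in the same deposited tables. TopHat2, HISAT2, STAR, StringTie and edgeR are named without versions or roles per the submitters' processing notes. Which of them made the deposited p-values is not given in the sources used here. The notes name the build hg18, but 53972 of the 54990 Ensembl transcripts found in GENCODE release 29 (98.1%) had the same chromosome, start and end there, which are GRCh38 positions. Coordinates are therefore printed as the files give them, as GRCh38 positions counted from 1. Whether reads of mouse origin were removed, and whether counting used the strand, is not given in the sources used here. Reads of overlapping and antisense genes may therefore not have been told apart.

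The tables held 63149 transcripts of 22947 genes. By GENCODE type, 24506 transcripts (38.8%) were retained introns and 18770 (29.7%) were processed transcripts, and 67.8% of all transcripts belonged to protein-coding genes. A gene-level value is the sum over a gene's tabulated non-coding transcripts and is not the level of its messenger RNA. Where such isoforms share sequence with the messenger RNA, its reads may have been assigned to them. A changed value of a protein-coding gene may therefore reflect a changed messenger RNA. A further 2558 transcripts were assembled by the authors, of which 1189 lay at loci with no annotated gene. All 3 per-number tables listed 46271 transcripts. The other 16878 were missing from at least 1 table and were taken as 0 there, which moved a pooled mean by at most 0.04 FPKM. Columns of per-sample values that could not be mapped to a sample numbered 0. No counts were used, so the sequencing depth of each library is unknown and no counting interval or detection floor is given. A transcript or gene at exactly 0 is described as listed at 0, and no fold change is printed against such a group.

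The values were tested as log2(FPKM + 0.5) with limma (empirical Bayes with an intensity trend), resistant against sensitive, with no further covariate. Features needed at least 0.5 FPKM in at least 3 of the 6 libraries, and a feature was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values are from limma unless the authors' deposited table is named. A fold change is on the log2(FPKM + 0.5) scale, which understates the change of low genes. Gene lists were tested with camera (preset correlation 0.01) where at least 3 members were measured, and with fry and an estimated correlation as alternatives. An estimated correlation also leaves camera far fewer degrees of freedom, those of the 6 libraries, so higher p-values there need not reflect correlation. fry tests whether a list's genes move, on balance, in 1 direction, and does not compare them with other genes. On simulated data with 200 changed genes among 10172, the gene-level test recovered 0%, 60%, 92% and 98% of genes changed by 1, 2, 3 and 4 on the log2 scale, with 2 false calls among 127. At the transcript level (21058 features) the shares were 0%, 12%, 66% and 94%, with 6 false calls among 92. Changes of 1 on the log2 scale in single genes were thus not detectable in the simulation with 3 libraries per group. Its errors were independent and equally spread over the 6 libraries, with no lower limit at 0 FPKM. In the real data resistant replicate 3 stood apart, so these shares and false calls need not hold there.

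The comparisons, the 16 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists covered lncRNAs linked to hypoxia, p53, snoRNA hosting, colorectal cancer, epithelial-mesenchymal transition and interferon. Others covered lncRNAs of hepatocytes, endothelium, fibroblasts and leukocytes, abundant structured RNAs, microRNA host genes, and genes whose symbols mark them as antisense, divergent, intronic or overlapping, or long intergenic. Named genes were the 10 with the largest change in each direction among called genes with a symbol whose groups did not overlap. To these were added up to 4 called members of each list (or, with none, the 2 most abundant), the 5 most abundant genes, entries named after SYTL5, and at most 2 called loci without a symbol in each direction. Genes named only because they passed the threshold over a list alone, or to complete a small count, fell outside the rule and were chosen after their values were seen. A member of the divergent list is not reported here by name. Lists of host genes (protein-coding genes whose non-coding isoforms were tabulated) were added after the data were seen and appear in the closing observations.

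Settings chosen beforehand for comparison were pseudocounts of 0.1 and 1, no filter, a filter at 1 FPKM, median centring, quantile normalisation, robust empirical Bayes, a false discovery rate of 0.1, the library number as a block, and leaving out each library in turn. For named genes, the most abundant transcript in place of the gene was also foreseen. Array weights, the removal of genes of protein-coding type, and the removal of each library's trend with GC content were added after the data were seen. The settings foreseen for count data (size factors and a count filter) were not run, because the files hold FPKM. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.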

Results

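Long non-coding transcripts were profiled in 6 xenograft libraries, 3 from bevacizumab-sensitive and 3 from bevacizumab-resistant HCT116 liver tumours. The study asked which lncRNAs accompany resistance to anti-angiogenic treatment, in which tumours can grow along existing vessels. The groups also differed in their treatment label (Day 0 against Day 42). Resistance therefore cannot be separated from the treatment itself or, as far as that label gives it, from time in the animal. Summed FPKM over all listed transcripts was 53839, 56852 and 55772 in sensitive replicates 1, 2 and 3, and 55805, 58070 and 72422 in resistant replicates 1, 2 and 3. The most abundant transcript held 1.17% to 1.29% of that sum in the sensitive libraries and 4.92%, 3.99% and 6.8% in resistant replicates 1, 2 and 3. Across transcripts on the log2(FPKM + 0.5) scale, Pearson's r of resistant replicate 3 with the other 5 libraries was 0.433 to 0.527, and the other 5 correlated with each other at 0.704 to 0.791. These correlations are across transcripts, which are not independent replicates. Principal component 1 (47.4% of the variance) placed resistant replicate 3 at 82.4 and the other libraries between -26.8 and -8.5. Component 2 (24.4%) placed the sensitive libraries between 15.6 and 28.1, resistant replicates 1 and 2 at -36.2 and -37.5, and resistant replicate 3 at 7.5.

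The SYTL5 locus, known from the study for the lncRNA SYTL5-OT4, was higher in all 3 resistant libraries. Summed over its 7 assembled non-coding transcripts, SYTL5 (a synaptotagmin-like Rab27 effector gene) stood at 0.916 ± 0.102 FPKM in sensitive and 11.3 ± 1.28 FPKM in resistant tumours (SD, n = 3 each). The change was 3.05 on the log2 scale (SE 0.271, adjusted p = 0.00264). SYTL5-OT4 itself was listed at 0 in the 3 sensitive libraries and stood at 1.80, 2.40 and 1.16 FPKM in resistant replicates 1, 2 and 3 (adjusted p = 0.0322). The transcript runs over X:37905983-38043058 (GRCh38). In GENCODE release 29 this span holds the lincRNA AL121578.3 (X:37906147-37949405) and the start of SYTL5 (X:38006582-38128819), both on the plus strand, and lies inside the annotated gene AF241726.2 (X:37349330-38687674). Among the other transcripts of the locus, SYTL5-OT1, SYTL5-OT2, SYTL5-OT3, SYTL5-OT5 and SYTL5-OT6 had non-overlapping groups, with adjusted p = 0.0959, 0.0864, 0.116, 0.127 and 0.101. SYTL5-OT7 did not reach the filter. In the authors' deposited table, SYTL5-OT4 had an adjusted p of 8.53e-07 and SYTL5-OT5 of 0.016, both as higher. The other 5 transcripts of the locus had adjusted p of 0.296 to 0.845 in the authors' deposited table. The gene-level call held when each library was left out in turn (adjusted p 0.00375 to 0.0314). The call of SYTL5-OT4 held only without resistant replicate 3, and its adjusted p reached 0.201 with other libraries left out.

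**Figure D1:**
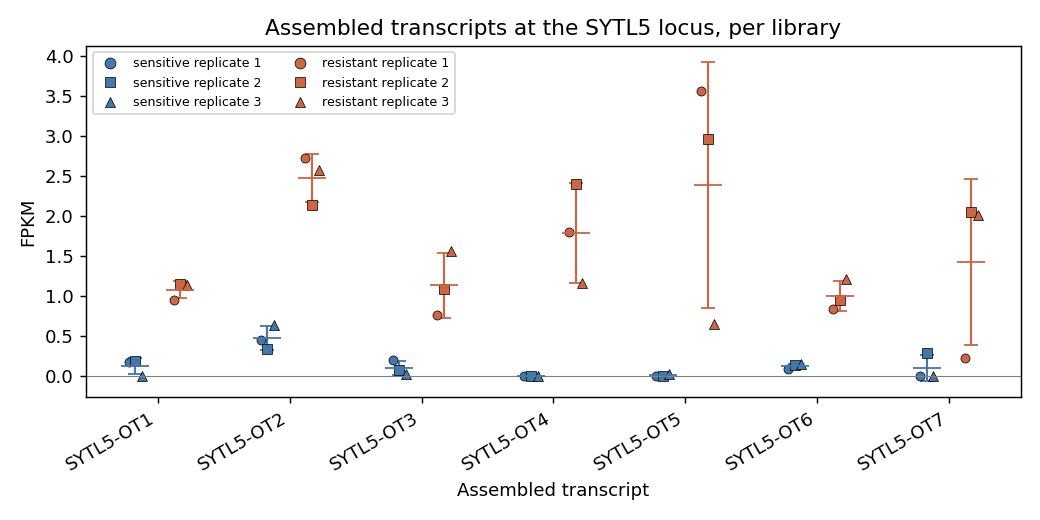
FPKM (vertical axis) of the 7 assembled transcripts of the SYTL5 locus, with points for single libraries, bars for the mean of 3 libraries per group and error bars for the SD. SYTL5-OT4 was listed at 0 in all 3 sensitive libraries and lay between 1.16 and 2.40 FPKM in the resistant ones.

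Resistant tumours carried higher non-coding transcripts of VIM, CACNA2D4 and DUSP6. VIM encodes the intermediate filament vimentin, and its non-coding transcripts (10:17229291-17235085) stood at 0.303 ± 0.298 FPKM in sensitive and 23.5 ± 15.3 FPKM in resistant libraries (SD, n = 3 each; log2 change 4.78, SE 0.472, adjusted p = 0.00397). CACNA2D4, a calcium channel subunit gene (12:1791963-1918666), stood at 0.319 ± 0.208 and 18.5 ± 4.19 FPKM (4.54, SE 0.333, adjusted p = 0.00238). DUSP6, a phosphatase gene that restrains ERK signalling (12:89349482-89351582), went from 0.483 ± 0.183 to 10.01 ± 7.09 FPKM (3.24, adjusted p = 0.0187). The protease inhibitor gene SERPINB1 (6:2835856-2841959) rose from 1.88 to 18.2 FPKM (3.01), and RESF1, linked to silencing of retroelements (12:31959370-31993103), rose from 3.70 to 25.05 FPKM (2.65). Among genes of lncRNA type, SH3PXD2A-AS1 (10:103745966-103755423) rose from 0.358 to 5.75 FPKM and AL445647.1 (13:87807634-87811232) from 0.0119 to 2.68 FPKM. CCDC144NL-AS1 (17:20868433-20994142) was listed at 0 in all sensitive libraries and stood at 3.30, 5.59 and 3.89 FPKM in resistant replicates 1, 2 and 3 (adjusted p = 0.00264). PLEC, the gene of the cytolinker plectin (8:143937664-143975219), was likewise listed at 0 and stood at 2.60, 1.70 and 7.06 FPKM (adjusted p = 0.0226). The called loci without a symbol lay at 6:161307143-161315272 (0.00992 to 3.40 FPKM) and 2:233168199-233180050, the latter listed at 0 in the sensitive libraries. CACNA2D4, DUSP6 and RESF1 lie on chromosome 12, whose 616 tested genes had a median change 0.405 above that of all genes. By windows of 20 Mb that difference was 0.485 around CACNA2D4 (0 to 20 Mb), 0.319 around RESF1 (20 to 40 Mb) and 0.109 around DUSP6 (80 to 100 Mb). Calls of DUSP6, SERPINB1, SH3PXD2A-AS1, PLEC, RESF1, AL445647.1 and both loci without a symbol ended when a single library was left out. Without sensitive replicate 1 each of these lost its call, with highest adjusted p over the left-out libraries of 0.112, 0.0527, 0.0663, 0.132, 0.0663, 0.0527, 0.065 and 0.0573. Leaving out sensitive replicate 2 also ended the calls of DUSP6, SH3PXD2A-AS1, PLEC, RESF1 and both loci, and sensitive replicate 3 those of DUSP6 and PLEC. Leaving out resistant replicate 1 ended those of SH3PXD2A-AS1 and PLEC, and resistant replicate 2 those of DUSP6 and SH3PXD2A-AS1.

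Resistant tumours carried lower non-coding transcripts of CYP24A1, the vitamin D 24-hydroxylase gene (20:54154370-54173416). These stood at 35.3 ± 8.09 FPKM in sensitive and 0.00838 ± 0.0145 FPKM in resistant libraries (SD, n = 3 each), a log2 change of -6.11 (SE 0.292, adjusted p = 0.000138) and the largest of all called genes. BMP4, a growth factor gene of the TGF-beta family (14:53955466-53956648), fell from 7.77 ± 1.21 to 0.358 ± 0.155 FPKM (-3.27, adjusted p = 0.00264). SMAD7, the gene of an inhibitory SMAD (18:48920027-48942807), fell from 6.38 ± 0.225 to 0.248 ± 0.223 FPKM (-3.24, adjusted p = 0.00336). The stem cell marker gene PROM1 (4:15968230-16083658) fell from 3.97 to 0.00775 FPKM, and DPP4, a cell surface peptidase gene (2:161994961-162073596), from 6.46 to 0.136 FPKM. ARHGAP29 (1:94148988-94195940) fell from 11.3 to 0.318 FPKM, and the polarity gene MPP7 (10:28125010-28238700) from 12.6 to 0.252 FPKM. AC016074.2 (8:125648327-126008930) fell from 15.6 to 1.32 FPKM. SPARC, a matricellular protein gene (5:151662488-151686975), averaged 4.43 FPKM in sensitive libraries and was listed at 0 in all resistant ones (adjusted p = 0.00776). The keratin gene KRT7 (12:52232520-52252341) stood at 10.3 ± 10.3 and 0.416 ± 0.0931 FPKM (adjusted p = 0.0488), a fall on chromosome 12 where the median gene lay higher. Loci without a symbol fell at 5:49611485-49616710 (3.79 to 0.278 FPKM) and 2:226368127-226375696 (1.07 to 0.0894 FPKM). The call of KRT7 ended with any of the 6 libraries left out (adjusted p 0.0578 to 0.138), and with a pseudocount of 1 (0.0739), median centring (0.0574), robust empirical Bayes (0.0529) or a filter at 1 FPKM (0.0541). The unnamed locus on chromosome 5 lost its call with a pseudocount of 0.1 (0.0629). MPP7 lost its call without sensitive replicate 1, sensitive replicate 2 or resistant replicate 1 (highest 0.0602), and SPARC and AC016074.2 lost theirs without sensitive replicate 1 (0.0529 and 0.0578). The calls of both loci without a symbol held only without resistant replicate 3 (highest 0.11 and 0.131).

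**Figure D2:**
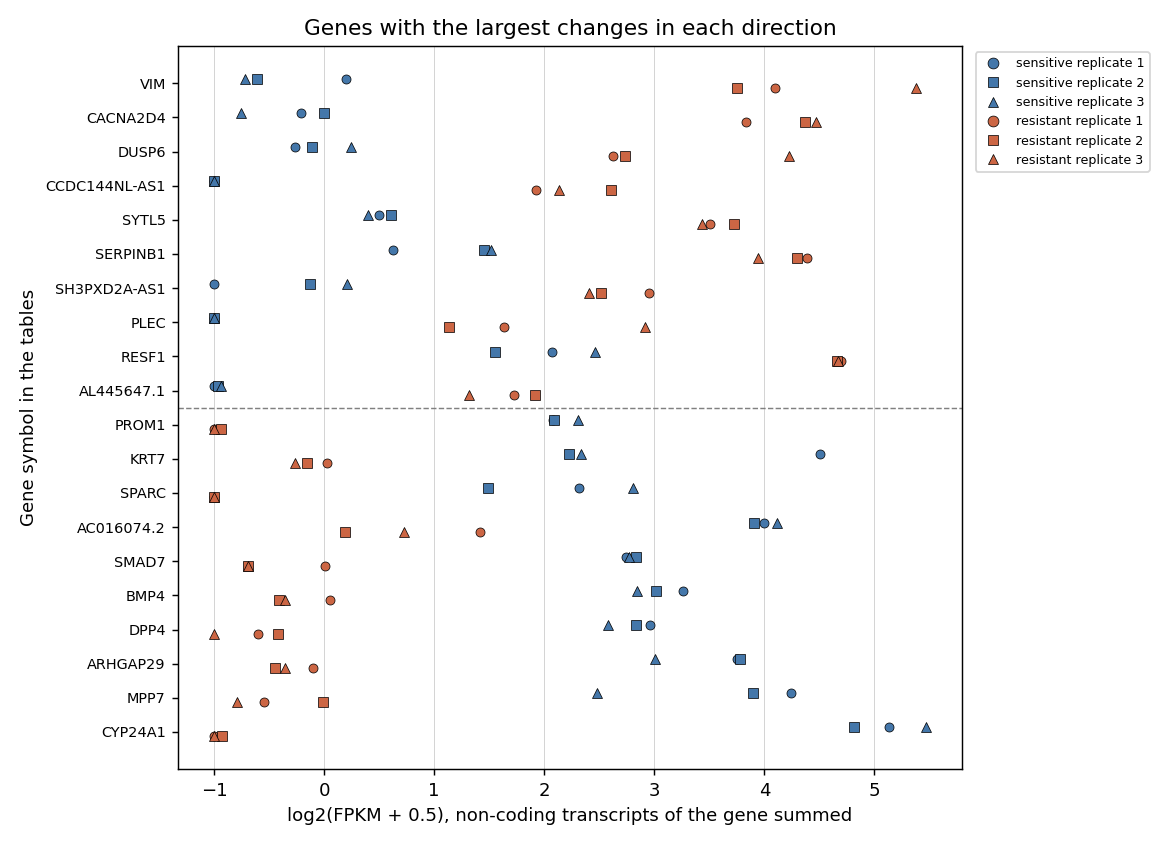
Level per library (horizontal axis, log2(FPKM + 0.5), summed over each gene's non-coding transcripts) of the 10 genes with a symbol and the largest changes in each direction, with colours for groups and shapes for replicate numbers. Sensitive and resistant points do not overlap for any of the 20 genes, which the rule for choosing them required. The lowest position, -1, is a value of 0 FPKM.

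In all, 104 of 10172 tested genes changed, 40 higher and 64 lower in resistant tumours, and 1343 had an unadjusted p under 0.05. Of these 104 genes, 66 were protein-coding genes with tabulated non-coding isoforms (23 higher, 43 lower) and 28 were lncRNA genes or pseudogenes (13 higher, 15 lower). For the 66, a change of the non-coding isoforms cannot be told from a change of the messenger RNA. Another 6 were assembled loci, and 4 were not in GENCODE release 29. At the transcript level, 56 of 21058 changed, 22 higher and 34 lower. The groups did not overlap for any of the 104 genes or 56 transcripts. Over all tested genes that share was 22.4%, where chance gives 10%. With 3 libraries per group a call almost requires separated groups, so the separation is not further support for the calls. The median gene lay 0.117 lower on the log2 scale in resistant libraries as deposited and 0.001 higher after removal of GC trends, and changes were not adjusted for this. The split of calls depended on scaling, with 48 higher and 49 lower after median centring and 67 and 57 after quantile normalisation. Without resistant replicate 3 the gene count was 196, and 95 of the 104 were among them. With sensitive replicates 1, 2 and 3 or resistant replicates 1 and 2 left out it was 16, 20, 43, 34 and 35, and the transcript count was 1, 6, 9, 24 and 25. Of the 34 named genes that were called, 11 kept their call with every library left out in turn. These were VIM, CACNA2D4, CCDC144NL-AS1, SYTL5, CYP24A1, ARHGAP29, DPP4, BMP4, SMAD7, PROM1 and LINC02331. With no filter 18 of the 34 lost their call, LINC02331 among them (adjusted p = 0.0739). When each gene was represented by its most abundant transcript 14 of 31 did, among them SYTL5 (0.0864), RESF1 (0.158), SH3PXD2A-AS1 (0.145) and MIR4500HG (0.0742).

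Divergent-transcript lncRNAs, read from promoters in the direction opposite to a coding gene, were lower as a group in resistant tumours, with 1 of 25 measured members at a log2 change above 0. Their median change was -0.48, against -0.12 for all genes (camera adjusted p = 0.000275, but adjusted p = 0.103 with an estimated correlation). EDRF1-DT fell from 1.46 to 0.172 FPKM and was the only member called (adjusted p = 0.0329). There were 5 lower when adjusted over the list alone, among them RAB30-DT (10.4 to 4.44 FPKM), MAP4K3-DT and NSMCE1-DT. Antisense lncRNAs were also lower as a group, with a median of -0.34 over 205 measured members, of which 57 lay above 0 (camera adjusted p = 0.0158, but adjusted p = 0.456 with an estimated correlation). That call also ended without sensitive replicate 2 (adjusted p = 0.0766) and without resistant replicate 3 (adjusted p = 0.324), which stood apart from the other libraries. Genes without a protein-coding type (2185 tested) had a median of -0.259, so part of both shifts was shared with such genes as a class. Neither list was tested against those genes alone. Of the antisense lncRNAs, 4 rose (CCDC144NL-AS1, SH3PXD2A-AS1, SLCO4A1-AS1 and RNF144A-AS1) and 2 fell (AZIN1-AS1, 2.21 to 0.349 FPKM, and NR2F2-AS1, listed at 0 in all resistant libraries). The counts adjusted over the list alone were 4 higher and 7 lower.

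Of 119 measured long intergenic lncRNAs, 3 rose and 2 fell, and the list was not called by camera (adjusted p = 0.412). LINC00460, a transcript described in colorectal tumours, rose from 1.21 ± 0.189 to 11.2 ± 6.38 FPKM (adjusted p = 0.0408). LINC01405, on chromosome 12, rose from 0.480 to 4.30 FPKM. LINC00397 was listed at 0 in all sensitive libraries and averaged 1.84 FPKM in resistant ones. LINC01031 fell from 3.15 to 0.147 FPKM and LINC02331 from 1.99 to 0.0108 FPKM. In this list 5 were higher and 3 lower when adjusted over the list alone. Among 15 microRNA host genes, MIR4500HG rose from 0.00986 to 1.96 FPKM and MIRLET7BHG from 0.114 to 1.05 FPKM, while MIR1915HG fell from 1.72 to 0.230 FPKM. Adjusted over the list alone there were 2 higher and 2 lower in that list (camera adjusted p = 0.989). Of 19 colorectal cancer lncRNAs, LINC00460 and SLCO4A1-AS1 (0.0253 to 2.29 FPKM) rose and none fell (camera adjusted p = 0.669). Adjusted over the list alone there were 3 higher, with LINC00659 added, and 6 lower, which were H19, MIR31HG, ZFAS1, UCA1, MNX1-AS1 and CRNDE. By fry, the long intergenic and colorectal cancer lists were past the threshold (adjusted p = 0.0138 and 0.0405), as were the antisense and divergent lists (0.0145 and 0.000637). The calls of LINC00460, SLCO4A1-AS1, MIRLET7BHG, MIR1915HG, AZIN1-AS1 and EDRF1-DT held only without resistant replicate 3, and their adjusted p reached 0.211, 0.187, 0.267, 0.16, 0.163 and 0.164. LINC01405 lost its call when any sensitive library was left out (highest 0.0947), MIR4500HG without sensitive replicate 1 (0.0527), and LINC01031 without sensitive replicate 2 (0.0537). Removal of GC trends also ended the calls of SLCO4A1-AS1 (log2 change 2.28 before and 2.15 after, adjusted p = 0.118) and MIRLET7BHG (1.34 and 1.05, adjusted p = 0.292). A pseudocount of 1 ended those of LINC00460 (0.053) and SLCO4A1-AS1 (0.0588), a pseudocount of 0.1 those of MIRLET7BHG (0.0699) and EDRF1-DT (0.0594), and median centring that of EDRF1-DT (0.0556).

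None of 12 hypoxia-responsive lncRNAs was called over all genes (camera adjusted p = 0.669, median -0.37). Its abundant members MALAT1 and PVT1 stood at 428 ± 68.8 and 89.7 ± 12.6 FPKM in sensitive and 506 ± 129 and 70.9 ± 12.2 FPKM in resistant libraries (adjusted p = 0.812 and 0.652). Adjusted over the list alone there were 1 higher, the paraspeckle RNA NEAT1, and 3 lower, which were H19, MIR31HG and UCA1. NEAT1, singled out after its values were seen, stood at 15.8 ± 3.30 and 66.7 ± 27.9 FPKM (log2 change 1.99, adjusted p = 0.0522 over all genes and 0.00665 over the list). Of 4 p53-induced lncRNAs none was called over all genes, and NEAT1 was the only member past the threshold when adjusted over the list alone. The median of that list was -0.31 and its mean 0.12, of opposite sign (camera adjusted p = 0.863). NORAD, in the same list, stood at 84.9 ± 2.54 and 48.9 ± 22.6 FPKM (adjusted p = 0.383). No member was called among 26 snoRNA host genes (camera adjusted p = 0.268), 8 lncRNAs of epithelial-mesenchymal transition (0.863), 5 of interferon and antigen-presentation loci (0.698) and 50 intronic or overlapping lncRNAs (0.412), and none was past the threshold when adjusted over the list alone. Their abundant members included SNHG29 (263 ± 42.3 and 257 ± 110 FPKM), GAS5 (93.4 ± 16.2 and 67.7 ± 30.5), CYTOR (19.8 ± 3.56 and 21.3 ± 8.39), HCG18 (9.22 ± 1.94 and 5.58 ± 1.70) and MUC20-OT1 (34.4 ± 6.18 and 28.1 ± 11.1). At the transcript level, and singled out after their values were seen, the CYTOR transcript ENST00000645257 averaged 1.71 FPKM in sensitive libraries and was listed at 0 in all resistant ones (adjusted p = 0.0404). The PVT1 transcript ENST00000657517 was listed at 0 in the sensitive libraries and averaged 2.15 FPKM in resistant ones (adjusted p = 0.0113). The call of the CYTOR transcript ended with any library left out (highest 0.18) and that of the PVT1 transcript with any sensitive library left out (highest 0.129). A p that misses the threshold does not show that levels were equal.

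Few markers of other cell types passed the filter. The lists name human genes, whereas the cells of the liver around these human tumours were of the mouse. Values of these lists therefore do not measure the amount of mouse cells. Of the hepatocyte lncRNAs only HULC was measured (1.34 ± 0.385 and 0.570 ± 0.201 FPKM, adjusted p = 0.308), and no endothelial lncRNA passed the filter. Of the fibroblast and mural lncRNAs, H19 stood at 1.72 ± 0.873 and 0.332 ± 0.233 FPKM (adjusted p = 0.197) and MIR100HG at 18.0 ± 2.27 and 15.1 ± 8.67 FPKM (adjusted p = 0.733). The only leukocyte lncRNA measured, TRG-AS1, stood at 0.871 ± 0.185 and 0.337 ± 0.138 FPKM (adjusted p = 0.281). HULC, H19 and TRG-AS1 were each lower when adjusted over the list alone, which for HULC and TRG-AS1 is their unadjusted p (0.0252 and 0.0199). The only structured RNA measured, RMRP, stood at 1.21 ± 0.0325 and 0.923 ± 0.452 FPKM (adjusted p = 0.699). These 5 lists had too few measured members for a list test.

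The 5 most abundant genes did not pass the test, and resistant replicate 3 stood apart in several of them. GSTA4 (6:52936101-52995944) averaged 454 ± 366 and 2034 ± 884 FPKM (adjusted p = 0.307), of which 99.5% came from GSTA4-OT1. That transcript overlaps the small nuclear RNA gene RN7SK (6:52995621-52995948). AL355075.4 (14:20343048-20343685), which overlaps the RNase P RNA gene RPPH1 (14:20343075-20343407), stood at 12.1 ± 3.71 FPKM in sensitive libraries and at 3.26, 27.7 and 4928 FPKM in resistant replicates 1, 2 and 3 (adjusted p = 0.621). AC006064.5 (12:6510275-6510522) lies within SCARNA10 (12:6510222-6510551) on chromosome 12 and averaged 678 ± 74.0 and 1004 ± 584 FPKM (adjusted p = 0.797). RPS18, a ribosomal protein gene, averaged 855 ± 52.7 and 588 ± 331 FPKM, with 206 FPKM in resistant replicate 3 (adjusted p = 0.566). An assembled locus on the scaffold KI270733.1 averaged 205 ± 31.1 and 849 ± 1100 FPKM, with 2118 FPKM in resistant replicate 3 (adjusted p = 0.58).

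The authors' deposited tables compared libraries of the same number and the pooled groups. In the authors' deposited tables for numbers 1, 2 and 3, 22996 of 54632, 23578 of 54646 and 31966 of 53919 transcripts were listed as different. Each such comparison rests on 2 libraries and compares those libraries, not the conditions. Of 46271 transcripts tested in all 3 of the authors' deposited tables, 1091 were listed as higher every time, against 395 for independent lists, and 1437 as lower, against 529. A further 3850, of 6378 listed in all 3 in any direction, had mixed direction. Listing also recurred where directions differed, so the excess over independent lists does not measure shared direction alone. Being listed in all 3 thus does not by itself show a shared direction. The authors' deposited pooled table listed 416 of 63149 transcripts, 167 higher and 249 lower. Of these 416, 404 were at 0 or absent in all 3 libraries of the lower group, 230 (55.3%) had a highest library under 0.5 FPKM, and 46 were among the transcripts tested here. Of the 416, 301 were above 0 in all 3 libraries of the higher group, 112 in 2 and 3 in 1. An example of the last kind, RPL7A-205, with 759 FPKM in resistant replicate 2 and 0 in the other 5 libraries, had an adjusted p of 0.0392 in the authors' deposited table. Of the 56 transcripts called here, 24 were on the authors' deposited list, and all 56 had the same direction in the authors' deposited table.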

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

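Array weights, the removal of genes of protein-coding type and the removal of GC trends were chosen after the data were seen, and the other settings were planned. The calls kept their sign under every setting in which they were tested. Against 104 genes and 56 transcripts, no filter gave 19 and 7, with 22925 and 63049 features tested, a false discovery rate of 0.1 gave 197 and 131, and array weights gave 347 and 179. The cause was not tested for array weights. Leaving out 1 library in turn gave 16 to 196 genes, 1 to 77 transcripts and 1 to 3 lists, with fewer samples in each fit. The highest gene and transcript counts came without resistant replicate 3, and the lowest without sensitive replicate 1. Against 2 lists, an estimated correlation gave 0, with camera's question unchanged but far fewer degrees of freedom. The fry test gave 4 and asks a different question of a list. Without genes of protein-coding type, 74 genes and 43 transcripts were called. Removal of GC trends gave 128 genes, 68 higher and 60 lower, and 70 of 88 testable calls were shared. With the library number as a block 29 genes, 1 transcript and 2 lists were called, and 14 of the 34 named calls ended. A pseudocount of 0.1 or 1 ended 3 each, median centring 2, removal of GC trends 2 of 27, robust empirical Bayes 1 and a filter at 1 FPKM 1 of 32. Representing a gene by its most abundant transcript ended 14 of 31, and using no filter ended 18. Deviations of same-numbered libraries correlated at -0.017, -0.128 and -0.18, and no sample correlated best with its own number. These values gave no sign of pairing. With 3 libraries per group, whose deviations are not independent, they cannot exclude it either. The unknown depth limits statements about low transcripts.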

Other observations

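The lists of host genes, the tests of splits, of library scale and of chromosome medians relative to all genes, and the removal of GC trends were chosen after the results were seen. The chromosome 12 pattern was itself noticed in these data. The other tests were written before their values were seen, although correlations over all transcripts were known when the test without abundant transcripts was written, and the membership of the ribosomal list was narrowed after its values were seen.

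Feedback genes of BMP and SMAD signalling were lower as a group in resistant tumours. Of 6 measured members, non-coding transcripts of SMAD7, ID3 (11.9 ± 1.32 to 0.960 ± 0.163 FPKM), BMP4 and SMAD6 (1.94 ± 0.636 to 0.0350 ± 0.0278 FPKM) fell. Over that list alone 5 were lower, with ID2 added, and MSX1 stood at 0.425 and 0.603 FPKM. The list's median was -2.62 on the log2 scale (camera adjusted p = 2.68e-08, adjusted p = 0.0404 with an estimated correlation, and 3.82e-06 without resistant replicate 3). Several members were seen among the largest changes before the list was written, so the list is not independent evidence. Of 6 feedback genes of MAPK signalling, DUSP6 rose, and over the list alone SPRY1 (0.936 to 2.52 FPKM), SPRY4 (11.9 to 25.6 FPKM) and SPRED2 did also (median 0.96, camera adjusted p = 5.77e-05, adjusted p = 0.0404 with an estimated correlation). That list was also written after some members were seen.

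Of 15 hypoxia-induced genes none was called over all genes, and over the list alone SLC2A1 (14.2 ± 2.18 to 65.1 ± 54.7 FPKM), ANGPTL4 (1.26 to 3.27 FPKM) and ANKRD37 (5.60 to 14.3 FPKM) were higher. The median of this list was 0.33 (camera adjusted p = 0.00437, adjusted p = 0.253 with an estimated correlation). Members went both ways, with 0 lower over the list alone. By library the list stood at -0.5, 0.14 and -0.2 in sensitive and 0.5, 0.02 and 0.1 in resistant replicates 1, 2 and 3, so the groups overlapped. Of 15 interferon-stimulated genes none was called (camera adjusted p = 0.0235, adjusted p = 0.445 with an estimated correlation, and 0.0638 without resistant replicate 3). The STAT2 transcript ENST00000652091, on chromosome 12, was called at the transcript level (0.00267 to 3.13 FPKM, adjusted p = 0.0173), a call that ended when any sensitive library or resistant replicate 2 was left out (highest 0.143). Mesenchymal genes went both ways, with VIM and CAVIN3 (0.299 to 3.25 FPKM) higher and SPARC lower (camera adjusted p = 0.538), and the list's median of -0.66 and mean of 0.25 differed in sign. Of 12 epithelial genes only PROM1 was called (0.602), and over the list alone the keratin genes KRT8 (123 ± 44.8 to 268 ± 69.0 FPKM), KRT18 (24.2 to 73.0 FPKM) and KRT19 (13.2 to 50.3 FPKM, groups overlapping) were higher, of which KRT8 and KRT18 lie on chromosome 12, and PROM1 and CLDN4 (1.54 to 0.602 FPKM) lower. Of 71 ribosomal protein genes only RPL22L1 was called, as lower (0.602), and in resistant replicate 3 their median lay at -0.54. Few host genes of other cell types passed the filter, which were CPS1 (4.01 and 2.62 FPKM) and HPX (0.598 and 1.25 FPKM) for hepatocytes, ESAM for endothelium, COL1A1 for fibroblasts and CORO1A for leukocytes. None of these 5 was called over all genes, with ESAM at 0.782 and 0.303 FPKM and CORO1A, whose groups overlapped, at 1.45 and 0.582 FPKM (adjusted p = 0.254 and 0.342). Each was the only measured member of its list, and over the list alone, which is then the unadjusted p, both were lower (0.0154 and 0.0369). The lists of other cell types again name human genes and do not measure the amount of mouse cells.

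Resistant replicate 3 stood apart from the other libraries. Its mean gene-level rank correlation (Spearman) with resistant replicates 1 and 2 was 0.72, against 0.878 between those 2, and a scale factor leaves ranks as they are. Without the 1% most abundant transcripts the transcript-level r was 0.452 against 0.736, so a few abundant transcripts do not account for it. Length and GC content accounted for 31.7% of the variance of its deviation, which correlated with GC content (Spearman 0.61) and not with length (-0.012), and removal of GC trends raised its gene-level Pearson's r from 0.757 and 0.746 to 0.833 and 0.831, against 0.905 before and 0.906 after between the other 2. A GC bias may thus be part of the difference but its share lies between the bounds set beforehand, and no biological explanation was tested.

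Genes on chromosome 12 lay higher in resistant tumours, as a gain of all or part of chromosome 12 would give. That is a hypothesis from these data alone, since copy number was not measured. Shuffling genes between chromosomes gave a permutation p of 0.0001 for chromosomes differing, the smallest that 10000 arrangements can give. That p treats genes as independent, does not measure the spread between tumours and is not specific to chromosome 12. The 616 tested genes had a median 0.405 above that of all genes (79.1% above it). It was uneven, with 0.497 (SE 0.037) at 40 to 60 Mb but 0.171 (SE 0.076) at 60 to 80 Mb and 0.109 (SE 0.161) at 80 to 100 Mb. Resistant replicates 1, 2 and 3 had 0.443, 0.453 and 0.378, so a single resistant library does not account for it. In resistant replicate 3, chromosome 19 lay higher still (0.728). Each value for chromosome 12 was set against the same 3 sensitive libraries, which were not examined singly. After removal of GC trends the median was 0.44 (SE 0.034) and that of the next chromosome 0.055, which argues against a GC trend. Of 103 calls, 83.5% (exact 95% interval 74.9% to 90.1%) stayed past the smallest called statistic after removal of chromosome medians, an interval reaching below the bound set beforehand, and 89.3% (81.7% to 94.5%) did when the medians were set relative to all genes. The largest such median lay 0.405 from that of all genes and the smallest called change was 1.26, so removal could hardly have ended most calls. Shifts of that size are too small to make up the called changes but may have carried some past the threshold. Chromosome 12 held 11 calls (1.79% of its genes), 9 of them higher, and the highest share was 2.79% on chromosome 13. Resistance, treatment and time in the animal stay open and untested as reasons for the shift.

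The divergent and antisense lists lay lower than other genes, although most tested genes (7987 of 10172) were protein-coding genes with non-coding isoforms. The 2185 genes without a protein-coding type had a median of -0.259, against -0.48 for the divergent and -0.34 for the antisense list. Without sensitive replicate 2 or resistant replicate 3 the antisense list was not called (camera adjusted p = 0.0766 and 0.324). Among 10000 sets matched on mean level alone, the higher percentile of the 2 list medians was 0.13, so a low level does not account for the lower medians. The sets were not matched on gene class. After removal of GC trends the higher adjusted p of the 2 lists was 0.00233, which argues against a GC trend. With an estimated correlation neither list was called. The estimate was -0.0237 for the divergent and 0.0215 for the antisense list against the preset 0.01. A positive correlation is thus not what ended the divergent call. That setting also leaves camera far fewer degrees of freedom, which by itself raises p. A difference tied to resistance, to treatment or to time in the animal also stays open and untested.

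For 39 called transcripts with other tabulated transcripts of their gene, 4 (10.3%, exact 95% interval 2.9% to 24.2%) had the others moving the opposite way, and 26 had them moving the same way by more than 1 on the log2 scale. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 104 genes, and the highest other split called 1, so that 1 split was as large, the real split included. For transcripts the values were 56 and 5, again with 1 split as large, and for lists 2 and 2, with 2 splits as large.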
